A study of Zea mays with 12 samples.

How the data were processed

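Total RNA from roots of maize seedlings, pooled from 6 plants per array, was labelled with Cy3 and hybridised to NimbleGen oligonucleotide arrays, per the labels. The 12 arrays fall into 4 groups of 3 (control without nitrogen, urea, nitrate, urea+nitrate) and sit on 1 slide. The probe intensities in the deposited files are on a linear scale and had already been normalised by RMA, per the submitters' processing notes, whose version is not given in the sources used here. All arrays share a single distribution of values: at 99.9972% of ranks the 12 arrays differ by under 1%. The deposited table of values equals the intensities of the array files. Raw scanner values were not used here. No pair of arrays was identical.

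Intensities were put on the log2 scale without further normalisation, and the 2 or 3 probes of an array target were summarised by median polish (at most 20 iterations). Of 59756 targets, 40256 had 2 probes, 19494 had 3 and 6 had 1. Targets belong to 39219 gene models, 11795 of them with more than 1 target. Gene names come from the RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, which matched 18691 models (47.7%) and named 2589. Of the matched models, 519 matched several genes. The build of the array's gene models is not given in the sources used here.

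The 95th percentile of the random probes served as the random-probe level of each array, and 29728 targets lay above it on all 12 arrays and 16670 on none. For a target above it on no array of a group, the bound on the fold sets the bright group's mean against the dim group's mean of, per array, the higher of the random-probe level and the target's own value.

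A linear model over all 12 arrays (limma 3.58.1, lmFit and eBayes, R 4.3.3, residual df 8, prior df 3.42) gave the 6 pairwise comparisons and the interaction of urea and nitrate. Benjamini-Hochberg adjusted p under 0.05 within a comparison counted as past the test. Every p in the report is an adjusted p from limma unless it is called unadjusted. The scripts also used the R package data.table (version 1.17.8) and Python 3.11.15. The steps were tested on simulated data of 59756 targets: in nitrate against control, 50% of 50 targets changed by 1 on the log2 scale, 94% of those changed by 2 and 100% of those changed by 3 passed, and in urea against control 30%, 82% and 98%. All 6 comparisons were simulated with the same means, spreads and number of arrays, so their shares differ by the random draw alone. The changes were planted together, and 134 and 112 targets passed in these simulations. The adjusted threshold is stricter where fewer targets pass, so these shares overstate recovery in a comparison with few calls.

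Gene lists were tested with limma's camera (preset correlation 0.01, adjusted over all lists), with an estimated correlation as the alternative. Of the 32 lists planned, 4 matched at least 5 gene models and 23 matched none, because the reference holds symbols and no descriptions. The planned lists that could be tested (aquaporins, glutathione transferases, heat shock proteins, jasmonate) passed in no comparison, with a lowest adjusted p of 0.125 for jasmonate in urea+nitrate against nitrate. The lists were therefore rewritten by symbol after the reference was seen and before any difference between groups was computed, giving 45 lists, of which 43 held at least 5 genes. In a list, each gene model counts once, at its brightest target, and is called a gene. Models matched to the same RefSeq gene were not merged.

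The groups, comparisons, threshold, alternatives and the rule for naming genes were chosen before the data were examined. By that rule, the text names, per comparison with control, up to 8 largest rises and 8 largest falls past the test (4 in other comparisons) among genes with a name whose 3 treated arrays all lie on the same side of the 3 reference arrays, 1 target per gene. It adds up to 4 members past the test per list, and the genes of nitrate transport, nitrate and nitrite reduction and asparagine synthesis in every comparison at their brightest target. DUR3 and urease were planned too but carry no name in the reference. Up to 2 unnamed transcripts in each direction are given, and for urea against control all 3 models, since the count was 5 or fewer and they were chosen after their values were seen. Shared calls were set against 100 simulations of groups without change that share their controls. Alternatives were cyclic loess, the mean of probes, removal of dim targets, a replicate block, only the 2 groups compared, an intensity trend with robust eBayes, a 2-fold threshold, each array left out in turn and, added after the data were seen, array weights.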

Results

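Transcript levels were measured in the roots of maize (Zea mays) seedlings of the hybrid PR33T56 that had been given different sources of nitrogen. Plants 5 days old were held for 8 h on a solution with 0.5 mM urea, with 0.5 mM calcium nitrate, with both, or with no nitrogen. The group with both received each at 0.5 mM, so it had more nitrogen in total than either source alone. No group separates the calcium of the nitrate salt from nitrate. Roots take up nitrate and reduce it to nitrite and ammonium, whereas urea can enter intact and be split to ammonium by urease, so the series sets an inorganic against an organic source. Each of the 4 groups held 3 single-colour oligonucleotide arrays, and each array measured the pooled roots of 6 plants. The labels call the 3 arrays of a group biological replicates from repeats of the experiment.

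An array carried 139000 transcript probes in 59756 array targets and 1663 probes of random sequence. Between 53.0% and 64.2% of the transcript probes lay above the 95th percentile of the random probes of their array, called the random-probe level here. A target not above that level on any array of a group has only an upper bound there, and its change is given as at least N-fold, from the bright group's mean against the random-probe level of the dim group. The number of arrays limits the precision, and the median standard error of a log2 difference between groups was 0.20. Levels below are log2 intensities with the SD over n = 3 arrays.

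Array control 1 stood apart from the other 11 arrays. On the first principal component, with 41.5% of the variance, it scored -154.6 where the others lay between -13.8 and 43.9. Across targets, which are not independent replicates, its correlation with the other controls was 0.943 and 0.940, against 0.978 to 0.993 for the remaining pairs within groups. The high-affinity nitrate transporter nrt2.2 read 9.81 in control 1 and 13.46 and 13.35 in the other controls, and the nitrate reductase gene NAR read 10.80 against 7.79 and 7.70. Values without control 1 therefore stand beside the calls it changed and the folds it moved by over 1.5 times.

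**Figure D1:**
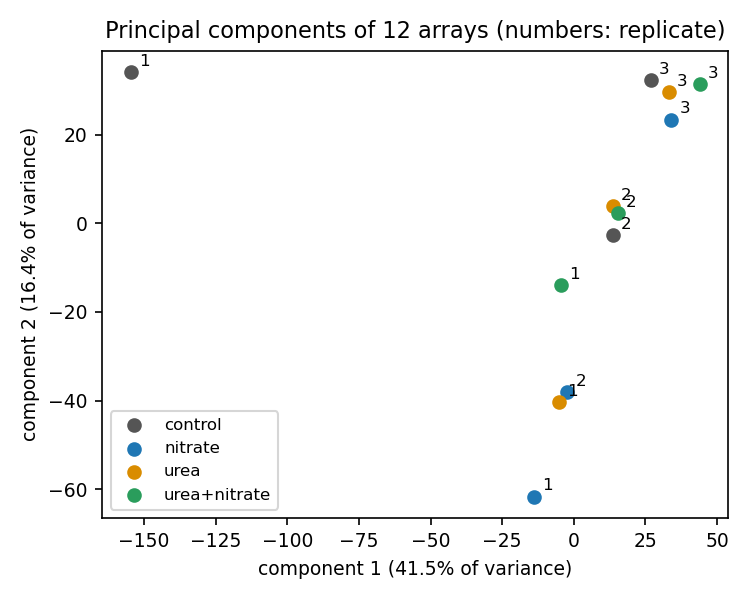
Scores of the 12 arrays on the first 2 principal components of all targets, coloured by group and numbered by replicate. Control 1 lies at -154.6 on the first component, which holds 41.5% of the variance, and the other 11 arrays lie between -13.8 and 43.9.

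Supplying nitrate after nitrogen-free culture asks which root transcripts respond to the inorganic source. The genes of nitrate and nitrite reduction rose. NAR (GRMZM5G878558_T01), a nitrate reductase gene, went from 8.76 ± 1.77 in control roots to 13.25 ± 0.22 with nitrate, 22.4-fold, and NNR1 (GRMZM2G568636_T01), a further nitrate reductase gene, from 9.68 ± 0.94 to 11.92 ± 0.32, 4.72-fold. NIR, the nitrite reductase gene, rose 10.01-fold at its brightest target (GRMZM2G079381_T05), from 10.04 ± 0.16 to 13.36 ± 0.06, and all 5 of its targets rose. sum1 (GRMZM2G105604_T01), which acts in the synthesis of siroheme, the cofactor of nitrite reductase, was not above the random-probe level in control roots and rose at least 2.81-fold with nitrate, to 9.59 ± 0.48. Adjusted p (limma, Benjamini-Hochberg) was 0.016 for NAR, 0.040 for NNR1, 6.2e-07 for NIR and 2.1e-04 for sum1, and in each case the 3 nitrate arrays lay above the 3 control arrays. Control 1 was the only control array with NAR above the random-probe level, and without it the log2 change was 5.50 in place of 4.48, at least 39.7-fold.

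Genes that feed electrons to nitrite reductase rose with them. The ferredoxin-NADP reductase gene fnr1 rose 4.49-fold (10.39 ± 0.27 to 12.56 ± 0.30, adjusted p = 0.013), the 6-phosphogluconate dehydrogenase gene pgd3 3.25-fold (12.98 ± 0.54 to 14.68 ± 0.08, adjusted p = 0.0069) and the ferredoxin gene FDX6 2.67-fold (8.97 ± 0.18 to 10.39 ± 0.11, adjusted p = 0.0045). The glutamine synthetase gene gln1 (GRMZM2G098290_T03), not above the random-probe level in control roots, rose at least 1.81-fold at 1 of its 2 targets, to 8.95 ± 0.37 (adjusted p = 8.0e-05). pdh2 (GRMZM2G043198_T04) rose 10.4-fold, from 7.68 ± 1.20 to 11.06 ± 0.24, with 2 of its 4 targets past the test (adjusted p = 0.016), and its log2 change was 3.38 with control 1 and 2.70 without it. Among transcription factor genes, GLK52, of the GARP family, rose 5.76-fold (8.42 ± 0.17 to 10.95 ± 0.27, adjusted p = 2.6e-05), LOB14, of the LOB-domain family, 2.47-fold at 1 of its 4 targets (9.82 ± 0.11 to 11.12 ± 0.31, adjusted p = 0.0086). HB34 rose at least 4.28-fold, with 1 of its 2 targets past the test, and TAZ1 at least 2.89-fold, with 4 of its 5 targets past the test. Hb2, for which the reference gives no product or gene family, rose at least 3.39-fold. Of transcripts without a gene name, GRMZM2G009223_T01 rose at least 4.51-fold and GRMZM2G071704_T01 10.8-fold, while GRMZM2G455124_T01 was at least 5.54-fold lower (adjusted p = 0.027) and GRMZM2G024196_T01 3.52-fold lower with nitrate (adjusted p = 0.013).

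**Figure D2:**
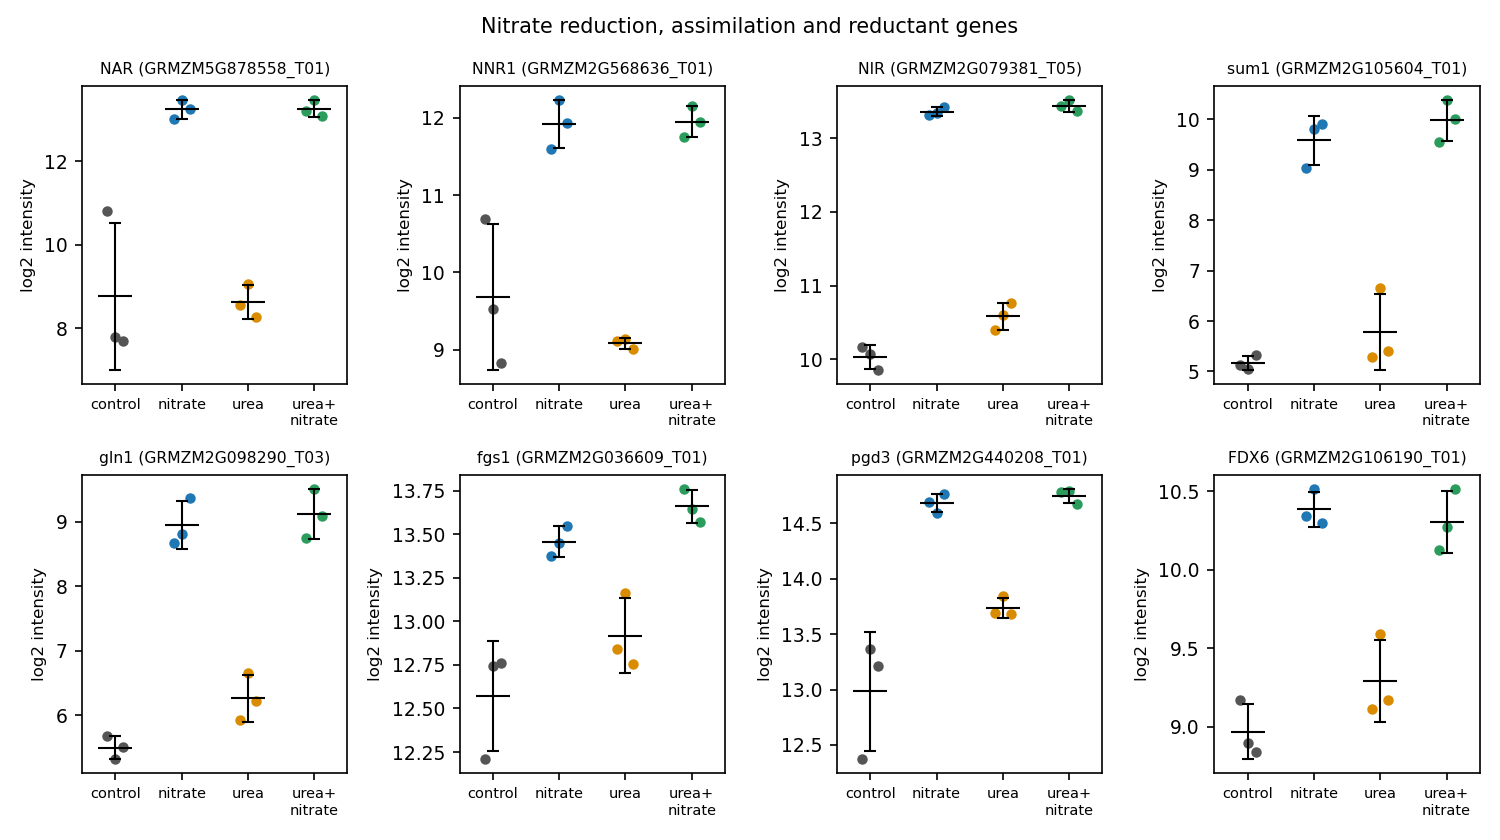
Log2 intensity of 8 array targets on each array (points) in the 4 groups, with the mean and SD of 3 arrays (bars). NAR lies at 13.25 in both groups with nitrate and at 8.76 and 8.63 in control and urea roots, and fgs1 lies at 13.66 in urea+nitrate and 13.46 in nitrate roots, a difference that did not pass the test.

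The nitrate transport genes did not pass the test. nrt2.2 read 12.21 ± 2.07 in control and 13.48 ± 0.40 in nitrate roots (log2 difference 1.27, adjusted p = 0.63; without control 1 0.08, adjusted p = 0.95, and without control 2 1.90, adjusted p = 0.37). GRMZM2G010280_T01, which the reference lists under both nrt2 and nrt2.2, read 10.63 ± 2.12 and 11.45 ± 0.33 (log2 difference 0.82, adjusted p = 0.77), with -0.40 without control 1 and 1.41 and 1.45 without control 2 or 3. NAR2.1, the partner protein of the transporter, read 12.12 ± 0.78 and 13.11 ± 0.38 (log2 difference 0.98, adjusted p = 0.48, and 0.53 without control 1). Of the asparagine synthetase genes, asn3 read 13.03 ± 0.97 and 12.60 ± 0.03 (log2 difference -0.43, adjusted p = 0.75, and -0.99 without control 1, adjusted p = 0.088) and AS 13.09 ± 0.39 and 13.04 ± 0.15. NAR2.2 and asn2 were not above the random-probe level in any group.

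In all, 79 targets were higher and 11 lower with nitrate, from 61 and 10 gene models, of which 16 carry a gene name. One of the lower targets belongs to DBP1a, whose level was not above the random-probe level in either group. At an unadjusted p under 0.05 there were 5327 targets, where chance gives 2987.8. Control 1 enters the control mean and the spread that all groups share, and targets are not independent. Such counts are therefore not a calibrated measure of change, here or in the comparisons below. Without control 1, 139 were higher and 88 lower and adjusted p was 1.3e-06 for NAR and 4.3e-04 for NNR1, whereas leaving out nitrate 2 left 46 targets in all and fitting only the 2 groups compared left 31. NAR and NNR1 missed the threshold without any other array of the 2 groups (adjusted p 0.064 to 0.12 and 0.074 to 0.26), as did pdh2 without any nitrate array (0.063 to 0.12), GRMZM2G024196_T01 without any nitrate array (0.055 to 0.10) and GRMZM2G455124_T01 without any array but control 3 (0.054 to 0.12). With the replicate number as a block, NNR1 also missed the threshold (adjusted p = 0.060). fnr1 missed it without control 2, control 3, nitrate 1 or nitrate 2 (0.064 to 0.10), and LOB14 without control 2, nitrate 1 or nitrate 2 (0.053 to 0.077).

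By gene list, the pentose phosphate and root ferredoxin list (3 of 5 genes rose, median log2 change 1.42, adjusted p = 6.9e-06) and the nitrate transport and reduction list (2 of 8 rose, median 0.90, adjusted p = 1.0e-04) were higher with nitrate, and both held with an estimated correlation between genes (adjusted p = 0.035 and 0.036). NAR is outside the second list because its name matched no pattern of it. Ribosomal proteins (38 genes, none past the test alone, median 0.33) were higher (adjusted p = 9.3e-07) but not with an estimated correlation (adjusted p = 0.61). The cell cycle list (37 genes) was higher (adjusted p = 0.0092), with adjusted p = 0.90 with an estimated correlation, 0.77 without control 1 and 0.13 without nitrate 3. Potassium transport (27 genes, median -0.19) was lower (adjusted p = 0.0092), with adjusted p = 0.47 with an estimated correlation and 0.060, 0.072 and 0.094 without control 2, control 3 and nitrate 1. These were the 5 of 43 lists past camera's test, 4 higher and 1 lower. Without control 1 there were 12, of which 5 were higher and 7 lower.

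Urea and nitrate together, against no nitrogen, moved the same nitrate genes. NAR rose 22.5-fold (to 13.25 ± 0.20, adjusted p = 0.013), NNR1 4.82-fold (to 11.95 ± 0.20, adjusted p = 0.029), NIR 10.6-fold (to 13.44 ± 0.08, adjusted p = 3.7e-07) and sum1 at least 3.68-fold (to 9.98 ± 0.41, adjusted p = 7.8e-05). fnr1 rose 4.45-fold, pgd3 3.40-fold and FDX6 2.52-fold (adjusted p = 0.011, 0.0043 and 0.0055), gln1 at least 2.03-fold, pdh2 9.33-fold and GLK52 6.48-fold. Without control 1 the log2 change of NAR was 5.51 in place of 4.49, at least 39.9-fold since the other controls were not above the random-probe level, and that of pdh2 2.54 in place of 3.22. HB34, Hb2 and TAZ1 rose at least 5.21-fold, 3.99-fold and 3.80-fold, and LOB14 2.02-fold (adjusted p = 0.037), with as many targets of gln1, pdh2, HB34, TAZ1 and LOB14 past the test as with nitrate alone. Among the genes with a name that the rule took, fgs1, CKX6 and HAK25 passed the test here and not with nitrate alone. fgs1, the ferredoxin-dependent glutamate synthase gene, rose 2.13-fold at 1 of its 2 targets (12.57 ± 0.31 to 13.66 ± 0.10, adjusted p = 0.026). CKX6, a cytokinin oxidase gene, rose 2.69-fold (10.16 ± 0.26 to 11.59 ± 0.09, adjusted p = 0.0023). The potassium transporter gene HAK25 was 1.80-fold lower at 1 of its 2 targets (11.87 ± 0.17 to 11.02 ± 0.13, adjusted p = 0.034). The difference between the groups with nitrate was itself tested and did not pass for any of them (log2 differences 0.20, 0.54 and -0.12). Of the transport and asparagine genes none passed: log2 differences were 1.42 for nrt2.2 (0.22 without control 1, 2.04 without control 2), 1.08 for GRMZM2G010280_T01 (-0.14 without control 1, 1.67 and 1.71 without control 2 or 3), 1.17 for NAR2.1 (adjusted p = 0.37), 0.14 for asn3 (-0.42 without control 1) and -0.06 for AS. Of unnamed transcripts, GRMZM2G009223_T01 and GRMZM2G071704_T01 rose at least 5.95-fold and 14.4-fold, and GRMZM2G107739_T03 and GRMZM2G388253_T04 were 3.79-fold and 3.72-fold lower (adjusted p = 0.0017 and 0.029).

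This comparison gave 122 higher and 19 lower targets (95 and 17 gene models, 21 with a name) and 4862 at an unadjusted p under 0.05, where chance gives 2987.8. Without control 1 it gave 211 higher and 94 lower, and without control 3 or urea+nitrate 1, 2 or 3 it gave 93, 73, 73 and 74 in all, and 30 when only the 2 groups compared were fitted. NAR, NNR1, LOB14 and HAK25 missed the threshold without any one array of the 2 groups except control 1 (adjusted p 0.053 to 0.080, 0.055 to 0.16, 0.10 to 0.18 and 0.067 to 0.17). pdh2 (0.072 to 0.11) and fgs1 (0.050 to 0.14) missed it without any urea+nitrate array, and fgs1 also without control 2. fnr1 missed it without control 2, control 3, urea+nitrate 2 or urea+nitrate 3 (0.055 to 0.074), and GRMZM2G388253_T04 without control 3 or any urea+nitrate array (0.055 to 0.17).

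The nitrate list (2 of 8 rose, median 1.13) and the pentose phosphate and ferredoxin list (3 of 5 rose, median 1.34) were higher with both sources, each at adjusted p = 5.6e-06 and at adjusted p = 0.015 with an estimated correlation. Ammonium assimilation (12 genes, fgs1 rose, 4 rose when adjusted over the list alone) was higher at adjusted p = 0.035, with adjusted p = 0.26 with an estimated correlation and 0.16, 0.067, 0.064 and 0.059 without control 1, control 2, urea+nitrate 1 and urea+nitrate 3. Ribosomal proteins (median 0.25, adjusted p = 1.1e-05), the cell cycle list (adjusted p = 0.017) and protein disulfide isomerases (15 genes, median 0.28, adjusted p = 0.022) were higher with no member past the test. Each had adjusted p = 0.87 with an estimated correlation, and without control 1 their adjusted p was 0.16, 0.86 and 0.69. Without urea+nitrate 3 the latter pair also missed the threshold (0.0995 and 0.059) and 3 lists passed in place of 6.

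Both nitrate-fed groups shared 77 higher targets, of 79 and 122, and 9 lower ones, of 11 and 19. Independent lists of these sizes would share 0.161 and 0.0035, and simulated groups without any change, set against the same control arrays, shared 9.64 and 12.61 on average over 100 simulations, a mean set by a single one with 964 and 1261. Across targets the log2 changes correlated at 0.791 (simulated mean 0.481), with a covariance of 0.0841 against a simulated 0.0374 (SD 0.0335). With 3 control arrays no split leaves a pair of control arrays for each comparison, and in the data control 1 is always among the shared controls. The simulated values may therefore be too low for these controls, and part of the excess may come from the shared controls. Without control 1 the shared higher targets numbered 130 and without nitrate 2 they numbered 46.

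Urea alone, against no nitrogen, changed few transcripts by the test. GRMZM2G049852_T01 rose 7.83-fold, from 8.04 ± 0.47 in control to 11.01 ± 0.51 in urea roots (adjusted p = 0.0095; of the controls only control 3 was above the random-probe level, and without it the rise was at least 6.66-fold), and GRMZM2G078472_T02 5.26-fold, from 8.62 ± 0.55 to 11.01 ± 0.20 (adjusted p = 0.024), with a second target of that gene model past the test. GRMZM2G001205_T01 rose 4.49-fold, from 8.83 ± 0.07 to 10.99 ± 0.32 (adjusted p = 0.0026), and also rose with nitrate, by 2.58 on the log2 scale (adjusted p = 3.6e-05). None of the 3 gene models carries a name in the reference used. All 4 targets also rose in urea+nitrate roots, where independent lists would share 0.0082. Of 100 simulations of groups without any change, with simulated controls shared between the comparisons, 1 shared any higher target, and it shared 4592 (mean 45.92). In nitrate against urea, a comparison without the control arrays, GRMZM2G078472_T02 passed the test (log2 difference -2.15, adjusted p = 0.0090) and GRMZM2G049852_T01 did not (-1.66, adjusted p = 0.082).

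**Figure D3:**
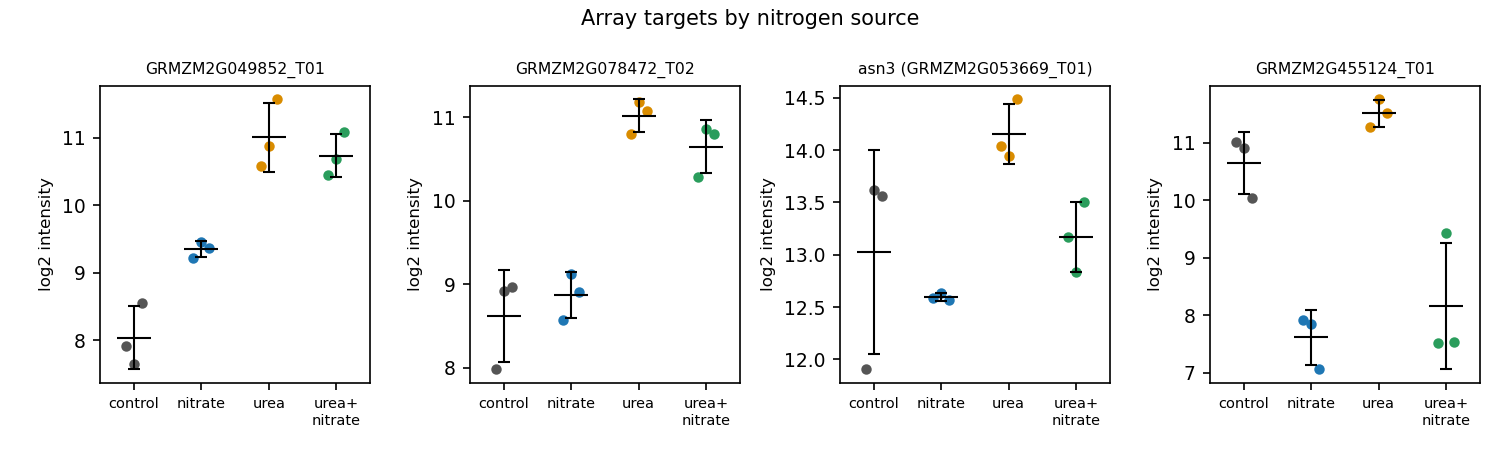
Log2 intensity of 4 array targets on each array (points) in the 4 groups, with the mean and SD of 3 arrays (bars). GRMZM2G049852_T01 and GRMZM2G078472_T02 lie at 11.01 with urea and at 8.04 and 8.62 in control roots, asn3 lies at 14.16 with urea and 12.60 with nitrate, and GRMZM2G455124_T01 at 11.51 and 7.61.

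The genes of nitrate use did not pass the test with urea. NIR read 10.04 ± 0.16 in control and 10.58 ± 0.18 in urea roots (adjusted p = 0.83), NAR 8.76 ± 1.77 and 8.63 ± 0.41 (log2 difference -0.14, adjusted p = 0.97, and 0.88 without control 1, adjusted p = 0.99), and asn3 13.03 ± 0.97 and 14.16 ± 0.29 (log2 difference 1.13, adjusted p = 0.83, and 0.57 without control 1). The log2 differences of nrt2.2 and NAR2.1 were 1.14 and 0.70 (adjusted p = 0.83 each) with control 1 and -0.05 and 0.25 without it, and that of nrt2.2 was 1.77 without control 2. GRMZM2G010280_T01, NNR1 and AS had log2 differences of 1.31, -0.60 and -0.28 (adjusted p = 0.83 each), and without control 1 of 0.09, -0.09 and -0.05, with GRMZM2G010280_T01 at 1.90 and 1.94 without control 2 or 3. No other target passed: 4 were higher and 0 lower by limma, with 3163 at an unadjusted p under 0.05 where chance gives 2987.8. Without control 1 the count was again 4, of which 3 were the same. Without control 2 it was 1, and without any urea array it was 2. With only the 2 groups compared in the fit, limma called 0. GRMZM2G049852_T01 missed the threshold without control 2 or urea 2 (adjusted p 0.052 and 0.055), and GRMZM2G078472_T02 without control 2 or any urea array (0.052 to 0.27). Ribosomal proteins (median 0.23, adjusted p = 0.0063) and the cell cycle list (adjusted p = 0.031) were higher, at adjusted p = 0.83 each with an estimated correlation. Without control 1 the direction of both turned (adjusted p = 0.91), and without urea 3 their adjusted p was 0.11 and 0.36. Against the 2 lists with all arrays, 5 passed without control 1, 4 without control 3 and 1 without urea 3.

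Nitrate against urea compares the sources directly. NAR was 24.6-fold higher with nitrate (13.25 ± 0.22 against 8.63 ± 0.41, adjusted p = 0.018), NIR 6.85-fold (13.36 ± 0.06 against 10.58 ± 0.18, adjusted p = 5.0e-06) and NNR1 7.14-fold (11.92 ± 0.32 against 9.09 ± 0.07, adjusted p = 0.011). sum1 was at least 2.76-fold and pdh2 (GRMZM2G043198_T02, 1 of 4 targets) at least 5.16-fold higher with nitrate, and fnr1, FDX6 and GLK52 were higher by 2.25, 1.09 and 2.24 on the log2 scale (adjusted p = 0.014, 0.038 and 8.5e-05). GRMZM2G455124_T01 was at least 10.1-fold higher with urea (adjusted p = 0.0066) and GRMZM2G078472_T02 4.42-fold (adjusted p = 0.0090, 1 of the 4 targets of its model). asn3, whose product makes asparagine from glutamine, read 14.16 ± 0.29 with urea and 12.60 ± 0.03 with nitrate, with all 3 urea arrays above the nitrate arrays. It did not pass the test in the fit of all 12 arrays (log2 difference -1.56, SE 0.38, adjusted p = 0.61) but did without control 1 (adjusted p = 0.0046), since that array widened the spread of asn3 that the groups share. nrt2.2, GRMZM2G010280_T01, NAR2.1 and AS differed by 0.13, -0.49, 0.28 and 0.22 on the log2 scale and did not pass (adjusted p = 1 each).

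Nitrate roots had 53 higher and 4 lower targets than urea roots (39 and 4 gene models, 13 with a name), and 1503 at an unadjusted p under 0.05, fewer than the 2987.8 that chance gives. Control 1 is not compared here but enters the shared spread, so a count under that of chance is no evidence against change. Without control 1 there were 102 higher and 26 lower targets, and without nitrate 2, nitrate 3, urea 2 or urea 3 there were 30, 31, 35 and 33 in all. NAR missed the threshold without any one of the 6 arrays (adjusted p 0.070 to 0.14), NNR1 without any but nitrate 1 (0.062 to 0.097), GRMZM2G455124_T01 without nitrate 3 or urea 2 (0.052 and 0.055), and GRMZM2G078472_T02 without nitrate 1, nitrate 3, urea 2 or urea 3 (0.054 to 0.069). Without control 1 adjusted p was 3.1e-06 for NAR and 1.4e-04 for NNR1.

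Of 7 lists past the test between nitrate and urea, pentose phosphate and ferredoxin was higher with nitrate (2 of 5 genes, median 0.94, adjusted p = 4.1e-07, and adjusted p = 0.016 with an estimated correlation). The nitrate list (2 of 8, adjusted p = 5.7e-04) had adjusted p = 0.053 with an estimated correlation and 0.070 without nitrate 3. Organic acid metabolism was lower with nitrate (17 genes, none past the test alone, median -0.14, mean -0.34, adjusted p = 0.0031, and adjusted p = 0.075 with an estimated correlation). Its largest difference was in PPCK1, which encodes a kinase of phosphoenolpyruvate carboxylase, at -1.53, followed by pep at -0.97. GARP transcription factors (10 genes, GLK52 past the test) were higher at adjusted p = 0.014, with adjusted p = 0.27 with an estimated correlation and 0.070, 0.056 and 0.060 without nitrate 3, urea 2 and urea 3. Ribosomal proteins were higher (adjusted p = 0.014), with adjusted p = 0.91 with an estimated correlation and 0.36, 0.41 and 0.057 without nitrate 3, urea 1 and urea 2. Potassium transport was lower (adjusted p = 0.014), with adjusted p = 0.27 with an estimated correlation and 0.26, 0.067 and 0.090 without nitrate 1, urea 1 and urea 2. Jasmonate genes were lower (46 genes, adjusted p = 0.020), with adjusted p = 0.84 with an estimated correlation and 0.16, 0.10, 0.23 and 0.13 without nitrate 1, nitrate 3, urea 1 and urea 3. In all, 3 lists passed without nitrate 3 and 4 without urea 1 or urea 2.

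Adding nitrate to urea raised the same reduction genes. NAR was 24.7-fold higher than with urea alone (adjusted p = 0.017), NIR 7.24-fold (adjusted p = 2.6e-06), NNR1 7.29-fold (adjusted p = 0.0092), sum1 at least 3.61-fold and pdh2 (GRMZM2G043198_T02, 1 of 4 targets) at least 5.43-fold. CKX6 was higher by 1.26, fnr1 by 2.23 and GLK52 by 2.42 on the log2 scale (adjusted p = 0.0092, 0.013 and 4.1e-05). GRMZM2G455124_T01 was 10.2-fold lower (11.51 ± 0.24 against 8.16 ± 1.10, adjusted p = 0.018) and GRMZM2G164967_T01 2.55-fold lower (adjusted p = 0.027). Without urea+nitrate 2, the only array of its group above the random-probe level for it, the log2 change of GRMZM2G455124_T01 was -3.99 in place of -3.35, at least 11.4-fold lower. asn3 read 14.16 ± 0.29 with urea and 13.17 ± 0.33 with both and did not pass (adjusted p = 1, and 0.077 without control 1), and nrt2.2, GRMZM2G010280_T01, NAR2.1 and AS, at log2 differences of 0.27, -0.23, 0.47 and 0.22, did not pass either. There were 60 higher and 4 lower targets (44 and 4 gene models, 13 with a name) and 1636 at an unadjusted p under 0.05, fewer than the 2987.8 that chance gives, with control 1 again in the shared spread. Without control 1 it was 133 and 14, and without any one of the 6 arrays compared between 33 and 42 in all. NAR missed the threshold without any one of those 6 (adjusted p 0.068 to 0.11), NNR1 without any but urea+nitrate 1 (0.054 to 0.069), and GRMZM2G455124_T01 and GRMZM2G164967_T01 without any but urea+nitrate 2 (0.076 to 0.13 and 0.12 to 0.17). Without control 1 adjusted p was 2.1e-06 for NAR. The nitrate list (2 of 8 higher, median 0.20, adjusted p = 6.4e-06) and the pentose phosphate and ferredoxin list (fnr1 higher, median 1.01, adjusted p = 1.4e-07) were higher and held with an estimated correlation (adjusted p = 0.016 and 0.013). Up to 5 lists passed with 1 array fewer, 5 of them without control 1 or urea+nitrate 3 and 4 without urea+nitrate 2.

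Adding urea to nitrate changed no target past the test, though 1 passed with the replicate number as a block. NAR, NNR1 and NIR differed by 0.01, 0.03 and 0.08 on the log2 scale, asn3 by 0.57, nrt2.2 by 0.14, GRMZM2G010280_T01 by 0.26, NAR2.1 by 0.19 and AS by -0.01 (adjusted p = 1 each). GRMZM2G078472_T02 was 1.78 higher with both sources than with nitrate alone and did not pass either (adjusted p = 0.88). limma called 0 targets, with 1393 at an unadjusted p under 0.05 where chance gives 2987.8, and the smallest adjusted p was 0.878. In the simulation of this comparison 38% of 50 targets changed by 1 on the log2 scale and 92% of 50 changed by 2 were recovered. In it 121 targets passed in all, and the adjusted threshold is stricter where fewer pass, so recovery is lower here. Changes of 1 were mostly not detectable with 3 arrays, and a change near 2, such as that of GRMZM2G078472_T02, could be missed too. Jasmonate genes were higher as a list with both sources (46 genes, none past the test alone, median 0.11, adjusted p = 0.013), with adjusted p = 0.88 with an estimated correlation. The list missed the threshold without nitrate 1, nitrate 3, urea+nitrate 1 or urea+nitrate 2 (adjusted p 0.057, 0.13, 0.23 and 0.21), and no list passed then, while 2 passed without nitrate 2 and 3 without urea+nitrate 3.

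Whether urea acted differently with and without nitrate was tested as the interaction of the sources. No target passed by limma, with 2158 at an unadjusted p under 0.05, where chance gives 2987.8, and a smallest adjusted p of 0.959. NIR, NAR and asn3 had interaction terms of -0.47 (SE 0.19), 0.14 (SE 0.90) and -0.56 (SE 0.54), and without control 1 those of NAR and asn3 were -0.88 and 0.01. The terms of nrt2.2, GRMZM2G010280_T01, NAR2.1, NNR1 and AS were -1.0, -1.05, -0.51, 0.63 and 0.27 (adjusted p = 0.96 each), and without control 1 0.20, 0.17, -0.06, 0.12 and 0.05. GRMZM2G001205_T01, which each source raised alone, had a term of -1.64 (SE 0.24, adjusted p = 0.96).

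**Figure D4:**
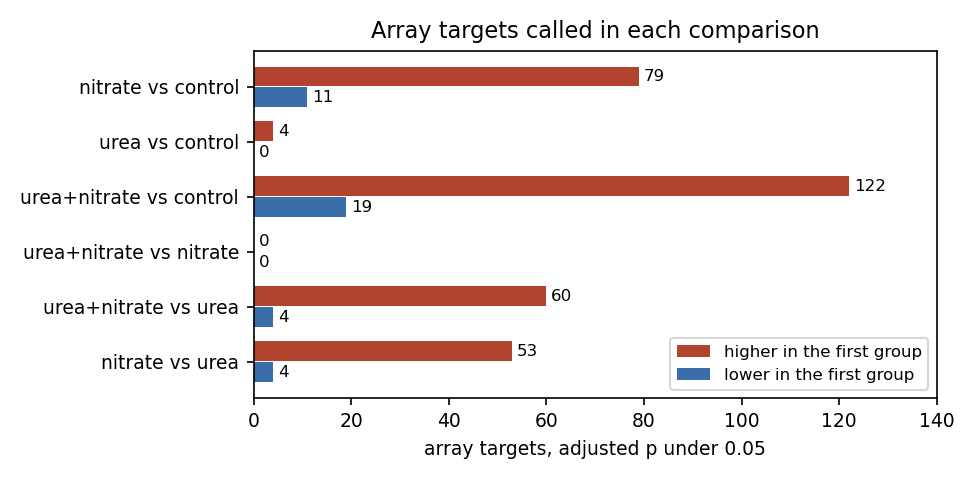
Number of array targets, of 59756, that passed the test as higher or lower in the first-named group of each pairwise comparison (bars, Benjamini-Hochberg adjusted p under 0.05). Comparisons of a group with nitrate against one without gave 57 to 141 targets, urea against control 4, and urea+nitrate against nitrate 0.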

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

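The tests of control 1 as a nitrate-supplied pool, of its most abundant leaf transcripts and of its effect on the urea count were chosen only after the result was seen.

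A pair of gene lists stood out because the effect of urea differed between roots with and without nitrate, by the interaction term. Ribosomal proteins (38 genes, none past the test alone, median -0.28) had an adjusted p of 0.0118 (limma, camera) and the abscisic acid and dehydration list (49 genes, none past the test alone, median 0.08) 0.0299. With an estimated correlation between genes these were 0.88 and 0.81, and without control 1 they were 0.52 and 0.41. For single targets, 100 of 100 drawn regroupings of the arrays called as many as the real 0, and the highest of the others was 0, but a real count of 0 fixes this outcome in advance, so it decides nothing.

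Control 1 stands apart from the other arrays. Over 53 targets higher with nitrate than with urea, control 1 lay at -0.12 on a scale from 0 (urea) to 1 (nitrate). This is a median, with quartiles of -0.24 and 0.05. For these targets the values argue against a nitrate-supplied pool under a control label. Controls 2 and 3 lay at -0.08 and -0.11. The fit that chose these targets includes control 1 in its spread, so targets on which it departed tended to drop out. NIR read 10.2 in control 1, near the other controls (10.1 and 9.9) and below nitrate roots (13.3 to 13.4). NAR and NNR1 read 10.8 and 10.7 in control 1, between the other controls and nitrate roots, and for them the question was not decided. A patch on the array surface as the reason is argued against, since a grid of blocks held 1.96% of the variance of its difference from its group. The other arrays had 2.75% to 17.2%, but of a smaller variance (0.097 to 0.312 against 0.724), so these shares do not rank the surfaces. Shoot tissue in the pool stays open: the photosynthesis list lay at percentile 51.85 among random lists, with CP24 2.33 higher and pep1 at -1.05 in control 1, and the small subunit genes of ribulose bisphosphate carboxylase, at most 0.24 higher, were not above the random-probe level there. No biological explanation was tested.

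Few transcripts passed with urea alone. The spread that control 1 adds could hide changes, but leaving it out again gave 4 targets, whereas nitrate against control went from 90 to 227, which argues against control 1 as the whole reason. A small response of the roots and changes too small for 3 arrays stay open, since 30% of simulated changes of 1 on the log2 scale were recovered in this comparison. In that simulation 112 targets passed, and with 4 passing the adjusted threshold is stricter and recovery lower.

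The splits of 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split alone gave as many targets (1 of 10) in nitrate against control (90, highest other 15), urea against control (4, other 0), urea+nitrate against control (141, other 0), urea+nitrate against urea (64, other 0) and nitrate against urea (57, other 0), and in urea+nitrate against nitrate all 10 splits gave 0. For lists, as many passed in 7 splits for nitrate against control (real 5, highest other 14), 9 for urea against control (2, other 12), 4 for urea+nitrate against control (6, other 9), 4 for urea+nitrate against nitrate (1, other 5), 5 for urea+nitrate against urea (2, other 3) and 1 for nitrate against urea (7, other 3). Splits that pass several times the real count of lists point to a structure of the samples, which was not tested.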

How the results depend on the processing

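Array weights, the planned lists in place of the rewritten ones, leaving out control 1 where control is not compared, every alternative for the overlap of calls and cyclic loess for named genes were tests chosen only after the result was seen. Cyclic loess, the mean of probes, removal of dim targets, the intensity trend with robust eBayes and the 2-fold threshold kept every count of targets within 1.5 times. Some of these could move little. For the 40256 targets with 2 probes the mean of probes is the main value itself. Cyclic loess started from arrays that already shared a distribution, and the 2-fold count is a part of the main calls. Cyclic loess kept 90 of 90 named-gene results. The counts moved in these settings, and the cause was not tested. Array weights gave 10112 targets for nitrate against control, 896 for urea+nitrate against control, 5029 for urea+nitrate against nitrate, 144 for urea+nitrate against urea, 456 for nitrate against urea and an overlap of 444, with weights from 0.121 (control 1) to 12.1 (nitrate 2). Only the 2 groups compared, with fewer arrays for the spread, gave 31 for nitrate, 0 for urea and 30 for urea+nitrate, each against control. The labels speak of repeats of the experiment but tie no replicate number to a repeat. Residuals of arrays with the same number correlated at 0.197 to 0.546, -0.078 to 0.167 and 0.298 to 0.428 for replicates 1, 2 and 3, against a mean of -0.128 for different numbers. Of 12 arrays, 9 correlated best with their own number, which is also a block of slide positions. The residuals of a group sum to 0, so the low values of replicate 2 do not speak against a shared block. The random-probe level also fell with the number, at intensities of 291 to 376, 248 to 312 and 208 to 227 for replicates 1, 2 and 3. With the replicate block, urea+nitrate against nitrate gave 1 target. The other counts stayed within 1.5 times, with 118 for nitrate and 175 for urea+nitrate against control. Of 90 named-gene results 89 kept their call, all but NNR1 in nitrate against control (adjusted p = 0.060).

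Each array of the groups compared, and control 1 in every comparison, was left out in turn. This gave 46 to 227 targets for nitrate against control, 1 to 4 for urea against control, 73 to 305 for urea+nitrate against control, 33 to 147 for urea+nitrate against urea, 30 to 128 for nitrate against urea, 0 throughout for urea+nitrate against nitrate and for the interaction, and an overlap of 46 to 130. Leaving out control 1 gave the highest value of each, with urea against control unchanged at 4. In 116 of 540 leave-one-out results a named gene lost its call, no called value reversed, and 63 of 90 results kept their side of the threshold throughout. Each result dropped only arrays of the 2 groups compared, and genes uncalled in comparisons without control were not counted. Among those, asn3 in nitrate against urea passed without control 1. Of 720 values recomputed for named genes, 23 uncalled ones changed sign. Lists past the test then numbered 4 to 12, 1 to 5 and 3 to 7 for nitrate, urea and urea+nitrate against control, 0 to 3 for urea+nitrate against nitrate, 2 to 5 for urea+nitrate against urea and 3 to 9 for nitrate against urea. With an estimated correlation they numbered 2 for nitrate against control, 0 for urea against control, 2 for urea+nitrate against control, 0 for urea+nitrate against nitrate and 1 for nitrate against urea. With all targets of listed genes 5 passed for urea against control and 7 for urea+nitrate against urea, and of the planned lists 0 passed in each of the 6 comparisons (camera). Not run were the deposited value table (identical values), no background correction (raw values not used here), median scaling (already a single distribution) and a slide block (1 slide). Signal over background limits dim targets, since 53.0% to 64.2% of probes lay above the random-probe level.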

Other observations

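No test in this part was chosen after the result was seen, since it reports values alone.

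The asparagine synthetase gene asn3 ordered the groups as urea 14.16 ± 0.29, urea+nitrate 13.17 ± 0.33, control 13.03 ± 0.97 and nitrate 12.60 ± 0.03 (n = 3 each), with control 1 at 11.9 and the other controls at 13.61 and 13.56. The place of control below urea+nitrate rests on control 1, since the other controls lay above the urea+nitrate mean. GRMZM2G455124_T01 was bright without nitrate (control 10.65 ± 0.54, urea 11.51 ± 0.24) and dim with it (nitrate 7.61 ± 0.47, urea+nitrate 8.16 ± 1.10). GRMZM2G049852_T01 read 9.35 ± 0.12 with nitrate, between control (8.04 ± 0.47) and both groups with urea (11.01 ± 0.51 and 10.74 ± 0.32).

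On the second principal component, with 16.4% of the variance, the replicate 3 arrays scored 23.4 to 32.4 and nitrate 1 scored -61.6.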
